A study of Mus musculus with 18 samples.

How the data were processed

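RNA was sequenced from 18 kidney samples of ICR mice aged 10 weeks, 3 in each of 6 groups, and 1 table of gene values was deposited. Per the labels, the tissue was frozen, total RNA was extracted with Trizol and a column kit, and libraries were made by standard Illumina protocols. The submitters' processing notes list Bowtie 0.12.2 and the mouse genome mm10; the counting tool, the annotation and any filter are not given in the sources used here. The deposited values are FPKM by the authors, a unit inferred from the values because no label or header names it. The sum of value times gene length over genes varied by 0.781% (coefficient of variation) over the 18 libraries, and the plain sum by 5.47%, which excludes values scaled to a common plain total. Whether single reads or fragments were counted is not stated. The table has 19545 entries with 19542 symbols, of which 3 stand on 2 entries each, and 18990 symbols were matched to the GENCODE mouse release 21 for coordinates and lengths.

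Read totals were not available, so the absolute depth is unknown and no counting interval can be given. From the smallest values of 55 to 126 genes per library, 1 read was worth between 1 and 1.14 times as much from library to library. The titles number the replicates 1 to 3 within each group, and each is a separate sample per the labels. Whether each comes from another mouse is not stated, so the p-values measure the spread between these samples, which may be technical.

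Genes with at least 1 FPKM in at least 3 libraries were kept, 12682 in all. Their values plus a pseudocount of 1 were put on the log2 scale, and all 18 libraries were fitted at once with 1 mean per group in limma 3.58.1 (R 4.3.3), with a trend in the prior variance and the robust option. This was the plan set for a normalized unit. The comparisons were STZ and AOS each with control, STZ+AOS, STZ+AOS-FMT and STZ+control-FMT each with STZ, the donors with each other, and the interaction, which is the effect of AOS with STZ minus that without. Adjusted p-values are by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Of 43 lists of genes, 41 had at least 4 tested members and were tested with camera at a preset correlation of 0.01 between genes, then with an estimated correlation and with fry. The 2 lists not tested were of neutrophil and mitochondrially encoded genes. Members of a list were also adjusted over the list alone. An exact permutation test of 3 against 3 cannot go under 0.1 and was not used for calls.

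Genes were named by a rule: among those past the threshold whose groups did not overlap, with a larger group mean of at least 1 FPKM and no predicted or clone symbol, the 10 with the largest rise and the 10 with the largest fall, or, where none passed, the 5 of each with the smallest p. Members of the lists could be named too. The position of each treated group between control and STZ was to be formed from genes chosen without the libraries scored. It could not be formed, because the held-out STZ libraries did not lie above the held-out controls. The gap between them is given in its place, a choice made after the data were seen.

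The fit was tested on simulated data of 12682 genes, 200 of them changed. The changed genes were drawn from those with a mean log2 value of at least that of 5 FPKM. At a log2 change of 1, limma recovered 81.5% for STZ, 82% for AOS, 81% for STZ+AOS, 78% for STZ+AOS-FMT, 84% for STZ+control-FMT, 83.5% for the donors and 57% for the interaction. At a log2 change of 2 these were 94.5%, 97.5%, 98.5%, 95.5%, 97.5%, 98% and 93.5%, with 4 to 14 false calls each. Simulated groups placed at 0, 0.5 and 1 between control and STZ came out at -0.00832, 0.495 and 0.999, and camera called each of the 3 lists raised by 1 and 0 others. The noise was drawn independently for each gene, whereas genes vary together in the real samples. The simulation therefore does not give the power or the rate of false calls, for genes or lists, in the real data.

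Alternatives were quantile normalization, median-of-ratios rescaling, no filter, a mean of at least 5 FPKM, limma without trend and robust, limma with weights for each library, pseudocounts of 0.1 and 5, a fit of only the groups compared, the replicate number as a block, and each library left out in turn. Chosen after the data were seen were rescaling to the total without Kap, Cyp11b1 as a covariate, the libraries with Cyp11b1 above 100 FPKM left out, and control 3 and STZ 1 both left out. Spermatid markers from outside the called genes were also listed after the data were seen. The values are not counts, so no model of counts was fitted.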

Results

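Gene expression was measured by RNA sequencing in 18 kidney samples from ICR mice aged 10 weeks. The samples fell into 6 groups of 3. These were controls, mice given AOS at 10 mg/kg (AOS), mice given STZ (STZ) and mice given STZ and AOS at 10 mg/kg (STZ+AOS). The last pair of groups had STZ and a transfer labelled AOS FMT (STZ+AOS-FMT) or control FMT (STZ+control-FMT), read here as the treatment of the donors. STZ is the usual abbreviation of streptozotocin, a toxin of pancreatic beta cells used to make rodents diabetic, and FMT that of faecal microbiota transplantation. The labels do not spell out AOS. The series was made to ask how such transfers act on a kidney damaged by STZ. Values are FPKM, fragments or reads per kilobase of gene length and of the reads assigned in each library, as mean ± SD (n = 3) or as the values of replicates 1, 2 and 3, and coordinates are those of mm10. Between 11407 and 12607 genes reached 1 FPKM in a library. Read totals were not available, so the depth is unknown. By the smallest values, 1 read was worth between 1 and 1.14 times as much from library to library. Values of 1.5 times the smallest of their gene or more were left out of this measure, so it cannot show that the depth was equal. A log2 difference is on the scale of log2(FPKM + 1), which understates changes of genes near 0, is given ± its standard error and was tested with limma over 12682 genes, adjusted by Benjamini-Hochberg. Sets of genes fixed before the data were examined were tested with camera at a preset correlation of 0.01, and a set is said to have risen or fallen relative to the other genes only when it passed at an adjusted p of 0.05. Parentheses after a set give, in this order, how many of its members lay on the called side, the median log2 difference of the set and the camera adjusted p.

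Kap (chromosome 6, 133849851 to 133853762), which encodes the kidney androgen-regulated protein of the proximal tubule, varied widely between samples of 1 group. Its FPKM was 144521, 155154 and 153075 in the AOS samples and 150876, 145522 and 15798 in the controls. It was 144830, 63552 and 14615 in the STZ samples and 6174, 35781 and 41198 in the STZ+AOS samples, and ranged from 54474 to 85880.2 in the 6 samples with a transfer. Cdkn1a, the p53 target that halts the cell cycle, went the opposite way. It was at 14.9, 7.11 and 82.6 in the controls and 3.73 to 5.20 in the AOS samples, 6.52, 62.5 and 80.1 in the STZ samples and 23.4 to 155 in the other 9 samples given STZ. Control 3 thus stood with the samples given STZ, and STZ 1 with those not given it. Each library was placed on an axis over 2635 genes that ran from 0 at the mean of the AOS samples to 1 at the mean of the 6 transfer samples. Controls 1, 2 and 3 lay at 0.0670, 0.0864 and 1.55, and STZ 1, 2 and 3 at 0.00360, 0.957 and 1.53. These genes and the axis were chosen after the values were seen, and any comparison with the controls or the STZ samples carries this arrangement.

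Transcripts of other tissues stood out in part of the samples. Cyp11b1 (chromosome 15, 74834125 to 74841643), the adrenal enzyme of the last step of corticosterone synthesis, was at 316, 14.3 and 276 FPKM in STZ+AOS, 0, 0 and 118 in the controls and 0, 5.13 and 5.13 in STZ, and at most 0.150 in the other 9. Star, which carries cholesterol into mitochondria for steroid synthesis, followed it, with 327, 17.5 and 310.5 in STZ+AOS and 0.750, 1 and 125 in the controls. Prm1 (chromosome 16, 10796326 to 10805839), a protamine that packs the DNA of sperm, was at 9.07, 9.44 and 14.5 FPKM in the controls and 20.8, 14.04 and 6.64 in the STZ samples, and was listed at 0 in the other 12 libraries. In all, 19 tested genes were higher in each of the 6 control and STZ libraries than in any of the other 12, among them the protamine genes Prm1 and Prm2 and the spermatid transition protein genes Tnp1 and Tnp2.

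**Figure D1:**
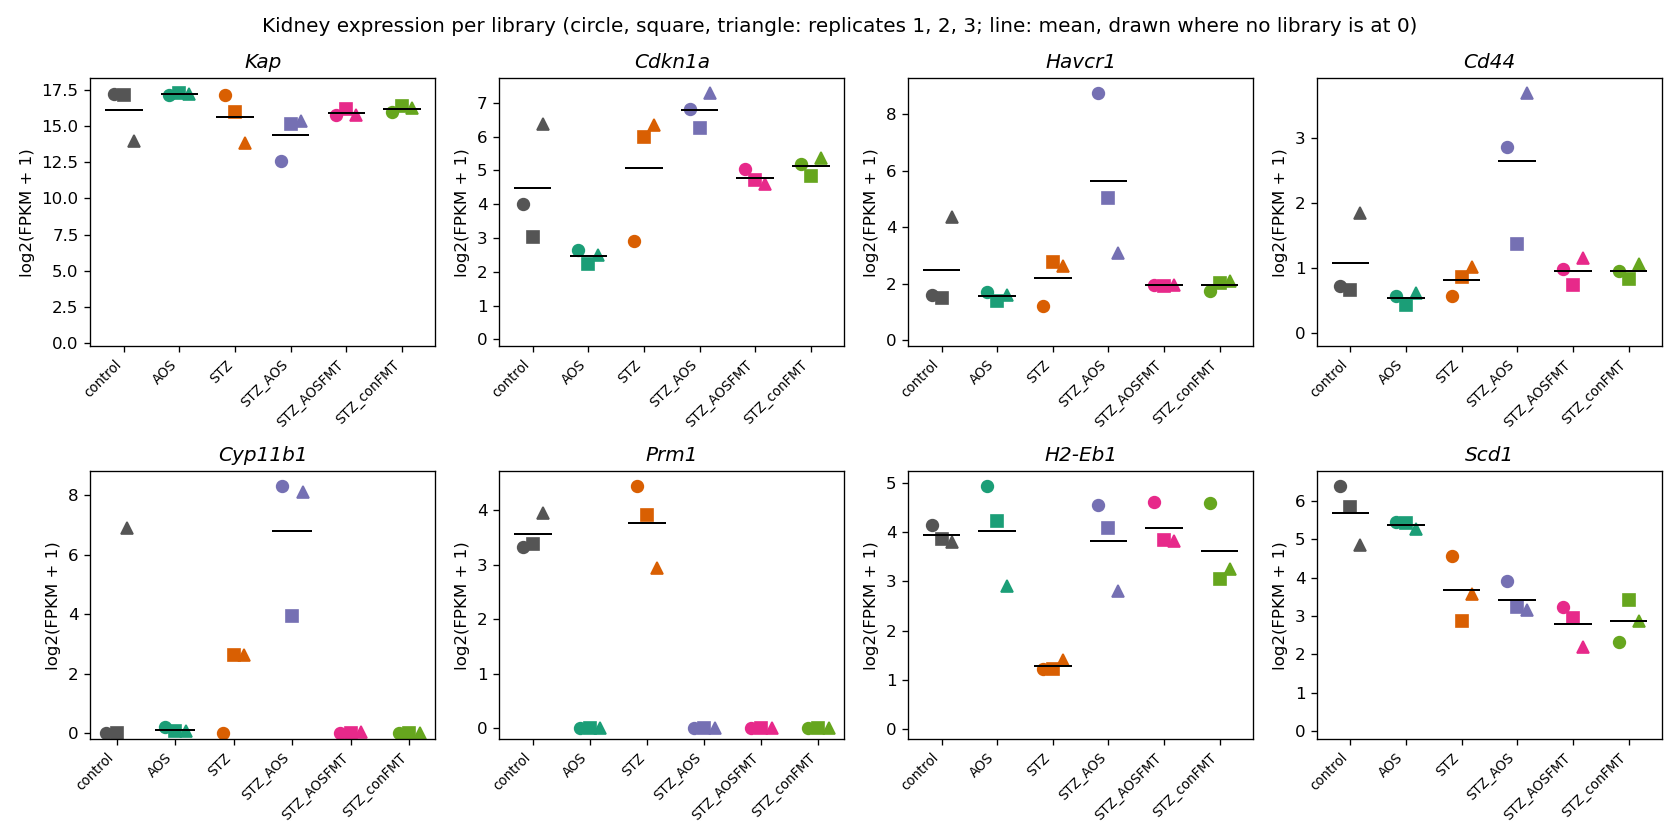
Each panel plots log2(FPKM + 1) of 1 gene on the vertical axis for the 3 libraries of each group, with circles, squares and triangles for replicates 1, 2 and 3 and a line at the group mean where no library is at 0. Control 3 and STZ 1 sit apart from their groups for Kap and Cdkn1a, Cyp11b1 is high in control 3 and in the STZ+AOS libraries, and Prm1 is above 0 in the control and STZ libraries.

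**Figure D2:**
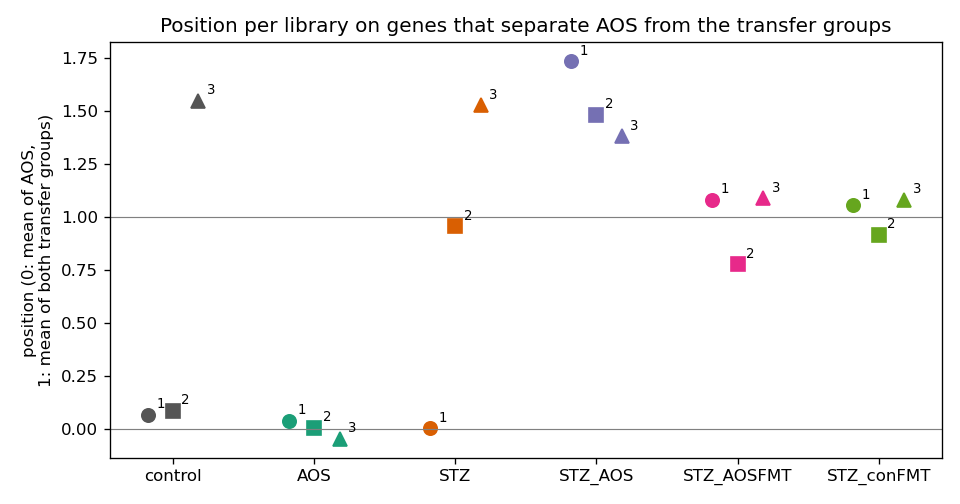
The position of each library, without unit, on the axis from the mean of the AOS libraries at 0 to the mean of both transfer groups at 1, over 2635 genes. Control 3 lies at 1.55 and STZ 1 at 0.00360, each apart from the other libraries of its group.

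**Figure D3:**
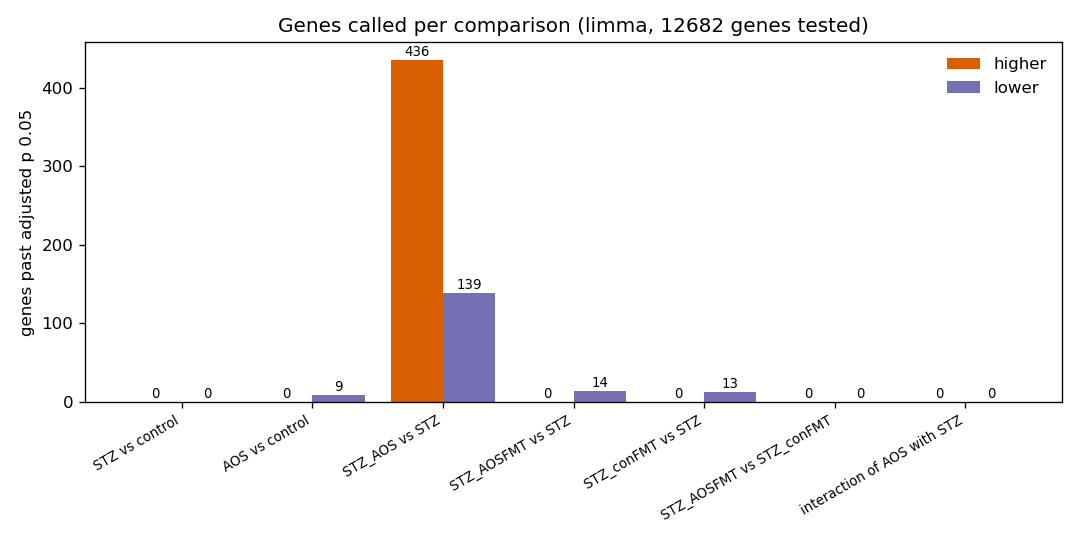
Bars give the number of genes, of 12682 tested with limma, that were higher or lower at an adjusted p under 0.05 in each comparison. STZ+AOS against STZ had 436 higher and 139 lower, and no other comparison had more than 14.

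The comparison of STZ with control asks what STZ did to the kidney. The genes of sterol and fatty acid synthesis fell as a group, with 16 of 18 members lower and a median log2 difference of -0.17 (camera adjusted p = 7.86e-05; adjusted p = 0.0993 with an estimated correlation). Scd1 (chromosome 19, 44394455 to 44407879), the desaturase that makes monounsaturated fatty acids, was at 55.3 ± 27.1 FPKM (n = 3) in the controls and 13.2 ± 8.29 in STZ, a log2 difference of -2.02 ± 0.44. Fasn, the fatty acid synthase, was at 19.1 ± 10.9 and 9.62 ± 6.54. H2-Eb1 (chromosome 17, 34305867 to 34316674), a chain of the class II molecules that present antigen, was at 14.4 ± 2.08 FPKM in the controls and 1.44 ± 0.179 in STZ, a log2 difference of -2.65 ± 0.51. Its neighbour H2-Ea-ps was at 14.8 ± 2.07 and 1.60 ± 0.525. None of these single genes passed over all genes (adjusted p = 0.714 for Scd1, 0.492 for H2-Eb1 and 0.669 for H2-Ea-ps). Adjusted over the list alone, 1 gene of sterol and fatty acid synthesis passed, Scd1 (adjusted p = 0.00608), and 1 of antigen presentation, H2-Eb1 (adjusted p = 0.00105). Over all genes the count was 0 in each list.

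A further 7 sets moved in STZ against control. Each of them had an adjusted p = 0.988 with an estimated correlation. The immediate early genes, which respond within minutes to stress or growth signals, rose (12 of 12 members higher, median 0.42, 7.34e-04), among them Egr1, with 11.7, 1.99 and 25.6 FPKM in STZ and 0.840, 1.92 and 11.5 in the controls. The ribosomal protein genes rose (23 of 23, median 0.12, 1.42e-04), as did the p53 targets (12 of 13, median 0.25, 0.0230), the endothelial markers (10 of 10, median 0.17, 0.0232) and the adipocyte markers (8 of 8, median 0.71, 0.0232). So did, by a median of 0.04, the nuclear genes of oxidative phosphorylation (20 of 23, 0.0442), whose direction turned under quantile normalization (adjusted p = 0.986). The markers of the thick ascending limb fell (7 of 9, median -0.21, 0.0230), with Umod, which encodes the most abundant protein of normal urine, at 874 ± 171 FPKM in the controls and 579.7 ± 63.9 in STZ. Over all genes and over each list alone, 0 members of these 7 sets passed.

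Over all genes, limma called 0 of 12682 genes for STZ against control, 161 had an unadjusted p under 0.05, and the smallest adjusted p was 0.130. The groups did not overlap for 3.23% of genes, where chance gives 10%. Rescaling by median of ratios also called 0 genes, quantile normalization 1 and limma with weights for each library 984. With control 3 and STZ 1 both left out, a choice made after the data were seen, 1105 genes passed, among them Scd1 at a log2 difference of -2.88 (adjusted p = 0.00199) and H2-Eb1 (adjusted p = 0.0329). The same choice lost the calls of the thick ascending limb (adjusted p = 0.595), adipocytes (0.733, direction turned), oxidative phosphorylation (0.922) and the immediate early genes (0.0724), so 4 of the 8 sets were called in it. Sterol and fatty acid synthesis was the only set called without each library in turn. For endothelium the call was lost without control 1, STZ 2 or STZ 3 (adjusted p up to 0.532, direction turned without control 1) and for p53 targets without control 1, control 2, STZ 2 or STZ 3 (adjusted p up to 0.396). For the thick ascending limb the call was lost without control 2, control 3, STZ 1 or STZ 2 (adjusted p up to 0.319) and for oxidative phosphorylation without control 2, control 3, STZ 1 or STZ 2 (adjusted p up to 0.678). For ribosomal proteins the call was lost without control 2 or STZ 3 (adjusted p up to 0.306) and for adipocytes without control 3, STZ 1 or STZ 3 (adjusted p up to 0.625, direction turned without control 3). For the immediate early genes the call was lost without STZ 1 or STZ 3 (adjusted p up to 0.177). Without control 2 the count of called sets went from 8 to 13. Median-of-ratios rescaling also lost adipocytes (0.0642) and oxidative phosphorylation (0.136).

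The comparison of AOS with control asks what AOS did without STZ. The proximal tubule markers rose (17 of 19 members higher, median log2 difference 0.24, camera adjusted p = 9.94e-08), and had an adjusted p = 0.556 with an estimated correlation. Slc22a8, an organic anion transporter, was at 128 ± 36.3 FPKM (n = 3) in the controls and 178 ± 19.5 in AOS. A further 8 sets were called, and with an estimated correlation organic ion transport had an adjusted p = 0.362 and the other 7 an adjusted p = 0.953. The androgen-responsive kidney genes rose with them (9 of 10, median 0.71, 8.13e-04), Kap being at 104065 ± 76489 and 150917 ± 5635. The p53 targets fell (13 of 13, median -0.46, 0.0164), with Cdkn1a at 34.9 ± 41.5 and 4.52 ± 0.740. So did the genes of fatty acid oxidation (20 of 23, median -0.28, 0.0492). Markers of the distal and connecting tubule (9 of 9, median -0.32, 0.0164) and of the intercalated cells, which secrete acid or base (9 of 9, median -0.36, 0.0351), fell as well. Small rises were called for T and NK cell markers (5 of 6, median 0.16, 0.0328), Y-linked genes (3 of 4, median 0.12, 0.0351) and organic ion and xenobiotic transport (9 of 14, 0.0164), whose median was 0.03 and mean -0.11, so that mean and test differ in sign. Over all genes and over each list alone, 0 members of these 9 sets passed.

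Without control 3, whose Kap was 15798 FPKM, 8 of the 9 sets lost their call and 5 sets in all were called. For the distal tubule the call was lost without AOS 1, control 1 or control 3 (adjusted p up to 0.261) and for intercalated cells without AOS 1, control 1 or control 3 (adjusted p up to 0.246). For T and NK cells the call was lost without AOS 1, control 2 or control 3 (adjusted p up to 0.121) and for Y-linked genes without AOS 2 or control 3 (adjusted p up to 0.682, direction turned without control 3). For fatty acid oxidation the call was lost without AOS 2 or control 1 (adjusted p up to 0.246) and for the proximal tubule without control 3 (adjusted p = 0.270). For the androgen-responsive genes the call was lost without control 3 (adjusted p = 0.807, direction turned) and for p53 targets without control 3 (adjusted p = 0.543). For organic ion transport the call was lost without control 3 (adjusted p = 0.439). Without control 2, 17 sets were called, and without AOS 3, 14. Median-of-ratios rescaling lost the calls of T and NK cells (0.162), Y-linked genes (0.0527), the androgen-responsive genes (0.0506) and organic ion transport (0.232), and quantile normalization those of the androgen-responsive genes (0.0986) and organic ion transport (0.244). The split of the sets depended on the scaling. It was 5 higher and 4 lower as reported, 1 and 13 after median-of-ratios rescaling and 3 and 14 after quantile normalization. The median of all genes was -0.095.

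Of single genes, limma called 9 lower and 0 higher in AOS, with 521 at an unadjusted p under 0.05. The spermatid genes Prm1 (adjusted p = 1.27e-05), Tnp2 (1.81e-04), Prm2 (7.68e-04), Oaz3 (0.00116), Tnp1 (0.0138), Spata4 (0.0123) and Fabp9 (0.0464) were listed at 0 in the 3 AOS libraries, where the controls had 9.07, 9.44 and 14.5 FPKM of Prm1. Ldhc, the lactate dehydrogenase of sperm, was at 1.56 ± 0.412 in the controls and 0.0233 ± 0.0404 in AOS (0.0432). Prm1, Tnp2, Prm2 and Oaz3 were called without each library in turn, and Tnp1, Spata4, Fabp9 and Ldhc were not (adjusted p up to 0.339). All 8 are among the 19 genes that were higher in each control and STZ library than in any other. The other called gene was Klk1b5 (chromosome 7, 44215945 to 44220703), a kallikrein-related peptidase, at 3.77 ± 0.636 and 1.85 ± 0.0902, a log2 difference of -0.74 ± 0.13 (adjusted p = 0.0464). It lost its call without any 1 of the AOS libraries and without control 1 or 3 (up to 0.344), and under both other scalings. So did Fabp9 and Ldhc, with adjusted p = 0.0811 each after median-of-ratios rescaling and 0.143 and 0.303 after quantile normalization, which also lost Tnp1 (0.0747) and Spata4 (0.130). Between 4 and 7 genes were called when 1 library was left out: 4 without AOS 1, AOS 2, AOS 3 or control 3, 5 without control 1 and 7 without control 2. Of the clock genes, 1 passed adjusted over the list alone, the repressor Cry1 (adjusted p = 0.0184), at 3.06 ± 0.686 FPKM in the controls and 0.913 ± 0.0321 in AOS, with an adjusted p of 0.582 over all genes.

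The comparison of STZ+AOS with STZ asks what AOS did in mice given STZ, and it held most of the single-gene changes. Among single genes, Slc22a6 (chromosome 19, 8618039 to 8628299), the main basolateral organic anion transporter, went from 462 ± 119 FPKM (n = 3) in STZ to 252 ± 55.4 in STZ+AOS, a log2 difference of -0.86 ± 0.22 (adjusted p = 0.0478). Slc13a3, the dicarboxylate transporter, fell from 339.8 ± 77.9 to 195 ± 49.5 (0.0374). Cd44, the hyaluronan receptor, rose from 0.773 ± 0.273 to 6.64 ± 5.23 (0.0420), Lox, which cross-links collagen, from 1.80 ± 1.48 to 6.65 ± 3.49 (0.0478), and the fibroblast receptor gene Pdgfra from 2.46 ± 1.08 to 5.78 ± 0.738 (0.0420). Without STZ 1, STZ 2, STZ+AOS 1 or STZ+AOS 3 these 5 genes lost their calls (adjusted p up to 0.224), except Slc13a3 without STZ 2. Quantile normalization kept only Pdgfra of the 5 (0.0636 to 0.106 for the others), and with control 3 and STZ 1 both left out none passed (0.0778 to 0.113). Havcr1 (chromosome 11, 46735080 to 46779578), the kidney injury molecule, was at 1.30, 5.87 and 5.16 FPKM in STZ and 423, 32.0 and 7.45 in STZ+AOS, a log2 difference of 3.42 ± 1.03 that did not pass (0.0606). Lcn2, secreted by injured tubules, was at 1.90, 6.19 and 44.2 and 772, 62.8 and 27.2 (0.0696), which did not pass either.

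In all, limma called 436 genes higher and 139 lower in STZ+AOS, and 4200 had an unadjusted p under 0.05. The groups did not overlap for 24.3% of genes, where chance gives 10%. The median of all genes was itself 0.19, so the medians of sets are given relative to it. The split depended on the scaling: 213 higher and 592 lower after median-of-ratios rescaling, 37 and 91 after quantile normalization. The 10 largest rises that met the naming rule were all genes known from the adrenal gland. They include the chromaffin granule genes Chga (4.42 ± 0.91, adjusted p = 0.0336) and Chgb (3.60, adjusted p = 0.0394) and the enzymes of catecholamine synthesis Th (3.36, adjusted p = 0.0288), Dbh (2.84, adjusted p = 0.0231) and Pnmt (3.48, adjusted p = 0.0335). The others were the neuropeptide gene Npy (4.40, adjusted p = 0.0497) and, of the cortex, the aldosterone synthase gene Cyp11b2 (3.41, adjusted p = 0.0359), the regulator Nr5a1 (3.10, adjusted p = 0.0497), the lipoprotein receptor Scarb1 (3.73, adjusted p = 0.0465) and Mrap (2.86, adjusted p = 0.0394). After quantile normalization Npy, Scarb1, Chgb, Cyp11b2, Nr5a1 and Mrap did not pass (adjusted p from 0.0536 to 0.0794). Cyp11b2 was at 0, 0.300 and 0.550 FPKM in STZ and 29.6, 1.54 and 30.1 in STZ+AOS. The 10 largest falls were the spermatid genes Prm1, Tnp2, Tnp1, Prm2, Fabp9, Oaz3, Meig1, Ldhc, Spata4 and Gsg1, with adjusted p from 5.82e-06 to 0.0120. Gsg1 lost its call without STZ 2 (adjusted p = 0.0577) and without STZ+AOS 1 (0.0525), and with Cyp11b1 as a covariate so did Tnp1 (0.0606), Meig1 (0.0675), Ldhc (0.184) and Gsg1 (0.299). Their log2 differences changed little with the covariate: -2.87 in place of -3.14 for Tnp1, -1.63 in place of -1.75 for Meig1, -1.48 in place of -1.49 for Ldhc and -1.28 in place of -1.29 for Gsg1. In all, 18 of the 575 called genes are among the 19 that were higher in each control and STZ library than in any other. H2-Eb1 rose from 1.44 ± 0.179 to 14.9 ± 8.40 (0.0336), with 13.0 to 16.8 in the controls, and lost its call without STZ 1, STZ 2 or STZ+AOS 1 (adjusted p up to 0.172).

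Of the sets, 6 fell and 6 rose in STZ+AOS against STZ. With an estimated correlation organic ion and xenobiotic transport passed (adjusted p = 0.0242), and the others had an adjusted p = 0.107 for oxidative phosphorylation and for the proximal tubule, 0.579 for the androgen-responsive and the vitamin D sets, and 0.767 for the remaining 7 sets called. The split of the sets depended on the scaling as that of the genes did: after quantile normalization 2 fell and 10 rose, 8 of them among these 12, and after median-of-ratios rescaling 4 and 9, 10 among these 12. The nuclear genes of oxidative phosphorylation fell (23 of 23 members lower, -0.39 relative to all genes, camera adjusted p = 1.22e-14). Over all genes 2 of them passed, Uqcrfs1 of complex III, from 316 ± 27.9 to 253 ± 20.1 FPKM, and Cox5a of cytochrome oxidase, from 678 ± 20.9 to 549 ± 8.82. There were 11 when adjusted over the list alone. The proximal tubule markers fell (18 of 19, -0.86, 8.74e-13), 2 over all genes and 11 adjusted over the list alone. The androgen-responsive genes fell as well (10 of 10, -1.02, 1.23e-04), with 0 by either count. Organic ion and xenobiotic transport fell (9 of 14, -0.56, 5.79e-05): 2 members passed over all genes, Slc22a6 among them, and adjusted over the list alone 4 fell and 1 rose, Abcb1a, an efflux pump. Erythroid markers (7 of 7, -0.54, 0.0302) and genes of vitamin D, phosphate and calcium (6 of 11, -0.32, 0.0319) fell. In the latter the member that passed, Fgfr1, a receptor of fibroblast growth factors, rose from 10.6 ± 1.35 to 16.2 ± 1.51 (0.0336). The adrenal cortex markers rose (8 of 8, 4.45, 0.00196), 2 over all genes and 8 adjusted over the list alone. The tubular injury genes rose (14 of 14, 1.30, 0.00333), Cd44 over all genes and 13 adjusted over the list alone, among them Havcr1 (0.0221) and Lcn2 (0.0221). Matrix genes (17 of 17, 0.56, 0.00498) rose, with Lox passing over all genes and 4 adjusted over the list alone. So did stromal and smooth muscle markers (10 of 10, 0.74, 0.0184), endothelial markers (10 of 10, 0.47, 0.00677) and cytokine and NF-kB genes (14 of 14, 0.48, 0.0401). Of these last, Pdgfra of the stroma and Ehd3 of the glomerular endothelium (adjusted p = 0.0478) passed over all genes, and 5 stromal, 10 endothelial and 5 cytokine genes adjusted over the list alone. The counts of members higher or passing stand against a wide background. Of all 12682 genes, 4200 had an unadjusted limma p under 0.05 here, and the median of all genes was 0.19. Uqcrfs1, Cox5a, Fgfr1 and Ehd3 lost their calls over all genes without STZ 1, STZ 2, STZ+AOS 1 or STZ+AOS 3 (adjusted p up to 0.224), and all but Fgfr1 after quantile normalization (0.0712 to 0.197).

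Among all 60 set calls over the 7 comparisons, the only ones that held with an estimated correlation were organic ion and xenobiotic transport in STZ+AOS against STZ (adjusted p = 0.0242) and in the interaction of AOS with STZ (adjusted p = 0.0189). The adrenal cortex markers were highest in STZ+AOS 1 and 3, with Cyp11b1 at 316, 14.3 and 276 FPKM. Whether these samples held adrenal tissue was not tested. With Cyp11b1 as a covariate, chosen after the data were seen, 7 genes and 7 sets were called. All 7 genes were lower, so that each of the 436 rises lost its call, with an adjusted p from 0.534 to 0.799 for Cd44, Lox, Pdgfra, H2-Eb1, Fgfr1 and Ehd3. The falls of Slc22a6, Slc13a3, Uqcrfs1 and Cox5a lost theirs too (0.595 to 0.812). In this fit the log2 difference of Cd44 was 0.65 in place of 1.83 and that of Slc22a6 -0.18 in place of -0.86. Those of H2-Eb1 (2.71 in place of 2.53) and Cox5a (-0.33 in place of -0.30) were not smaller, yet both lost their calls. Cyp11b1 was higher in each STZ+AOS library than in each STZ library, so the covariate overlaps with the comparison itself. A lost call alone therefore does not tie a gene to the adrenal markers. Of the 12 sets above, 3 passed with the covariate, oxidative phosphorylation, matrix and the stromal set, and 9 did not (adjusted p from 0.0844 to 0.913), with the direction turned for the adrenal, erythroid and androgen-responsive sets. The adrenal set holds Cyp11b1 itself, so the loss of its call was largely fixed in advance and decides nothing. Without STZ 1, which stood with the samples not given STZ, 11 genes were called, and without it and control 3, 20. Then the 10 named adrenal genes did not pass (adjusted p from 0.0767 to 0.130), and 16 sets were called, erythroid markers not among them (adjusted p = 0.0784). The count was 11 without STZ 2, with 0 genes higher both there and without STZ 1, 3349 without STZ 3, and 15, 1392 and 194 without STZ+AOS 1, 2 and 3. In a fit of these 6 libraries alone limma called 0 genes. The named adrenal genes lost their calls without STZ 1, STZ 2 or STZ+AOS 1 (adjusted p up to 0.224), and 8 of the 10 also without STZ+AOS 3. Without each library in turn, 7 of the 12 sets were called. For erythroid cells the call was lost without STZ 1, STZ 3 or STZ+AOS 1 (adjusted p up to 0.496) and for cytokines without STZ 3 or STZ+AOS 1 (adjusted p up to 0.294). For vitamin D, phosphate and calcium the call was lost without STZ 3 or STZ+AOS 1 (adjusted p up to 0.204) and for stroma and smooth muscle without STZ+AOS 2 (adjusted p = 0.143). For endothelium the call was lost without STZ+AOS 3 (adjusted p = 0.0542). Quantile normalization lost the calls of erythroid cells (0.457), the androgen-responsive genes (0.0643), vitamin D, phosphate and calcium (0.327) and organic ion transport (0.0784), and median-of-ratios rescaling those of erythroid cells (0.368) and vitamin D, phosphate and calcium (0.148).

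**Figure D4:**
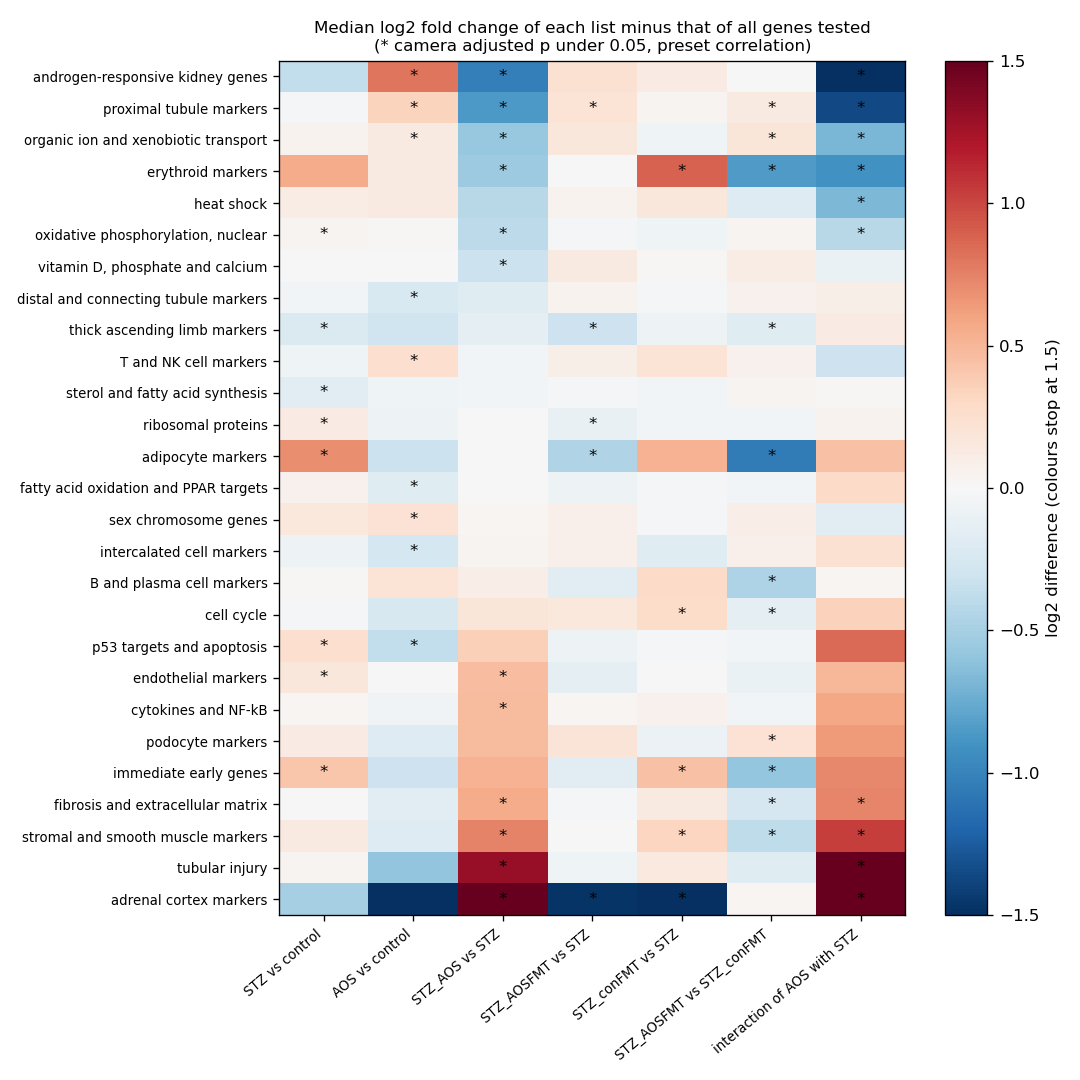
Each cell shows, for 1 gene set (vertical axis) and 1 comparison (horizontal axis), the median log2 difference of the set's tested members minus that of all genes, by colour, and a star marks a camera adjusted p under 0.05. Adrenal cortex and tubular injury are the most raised sets in STZ+AOS against STZ, at 4.45 and 1.30, and the proximal tubule and androgen-responsive sets are lowered there, at -0.86 and -1.02.

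The interaction asks whether the effect of AOS differed between mice with and without STZ. The proximal tubule markers differed most in p, their response being lower with STZ for 18 of 19 members (-1.36 relative to all genes, camera adjusted p = 1.31e-14, and adjusted p = 0.0993 with an estimated correlation). Of the 9 other sets called, organic ion transport held with an estimated correlation (adjusted p = 0.0189). The rest had an adjusted p with it of 0.495 for oxidative phosphorylation, 0.524 for the androgen-responsive genes and 0.825 for the other 6. Slc22a6 was at 446 ± 140.1 FPKM (n = 3) in the controls and 551 ± 19.1 in AOS, against 462 ± 119 in STZ and 252 ± 55.4 in STZ+AOS, a difference of log2 differences of -1.22 ± 0.32 (adjusted p = 0.0771). The response was also lower for organic ion transport (9 of 14, -0.68, 2.17e-05), the androgen-responsive genes (10 of 10, -1.85, 6.17e-06), oxidative phosphorylation (19 of 23, -0.42, 5.64e-08), heat shock (8 of 10, -0.68, 0.0307) and erythroid markers (7 of 7, -0.91, 0.0487). It was higher for the adrenal cortex (8 of 8, 6.42, 0.00175), tubular injury (14 of 14, 2.11, 0.00350), matrix (17 of 17, 0.73, 0.00350) and stromal sets (10 of 10, 1.03, 0.0295). For the adrenal markers, a response of the kidney is not shown, since the adrenal tissue held by each sample was not measured. Cd44 is an example from the injury set, with 1.29 ± 1.15 in the controls, 0.457 ± 0.0971 in AOS, 0.773 ± 0.273 in STZ and 6.64 ± 5.23 in STZ+AOS (0.0771).

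Over all genes limma called 0 for the interaction, with 4240 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0594, that of Nat8f1, an acetyltransferase gene named after its values were seen. Both other scalings also gave 0. The median of all genes was 0.29. Adjusted over the list alone, 10 proximal tubule genes, 3 of organic ion transport, 8 adrenal, 11 injury, 9 matrix and 6 stromal genes passed, against 0 over all genes. Without STZ 3 the count of genes was 3044, 793 without STZ+AOS 2 and 1 without STZ 2, and with the weights for each library it was 56. Of the 10 called sets, 4 were higher and 6 lower, against 15 and 2 after quantile normalization (6 shared) and 12 and 4 after median-of-ratios rescaling (8 shared). Here too 7 sets were called without each library in turn, but with control 3 and STZ 1 both left out 1 of these 7, the androgen-responsive genes, lost its call (adjusted p = 0.0678), as did heat shock (0.739) and erythroid markers (0.435). With Cyp11b1 as a covariate 4 of the 10 sets passed, proximal tubule, oxidative phosphorylation, matrix and stroma, and 6 did not (adjusted p from 0.0528 to 0.892), with the direction turned for the adrenal, erythroid, androgen-responsive and heat shock sets. The loss of the adrenal set, which holds Cyp11b1 itself, was again largely fixed in advance. For erythroid cells the call was lost without AOS 1, AOS 2, control 1, control 3, STZ 1, STZ 3 or STZ+AOS 1 (adjusted p up to 0.362) and for stroma and smooth muscle without AOS 2, control 1 or STZ+AOS 2 (adjusted p up to 0.130). For heat shock the call was lost without AOS 3, control 1, control 3, STZ 1 or STZ+AOS 2 (adjusted p up to 0.245). Quantile normalization lost the calls of erythroid cells (0.585), oxidative phosphorylation (0.579), heat shock (0.707) and organic ion transport (0.0710), and median-of-ratios rescaling those of erythroid cells (0.499) and heat shock (0.357).

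The comparison of STZ+AOS-FMT with STZ asks what a transfer from AOS-labelled donors did in mice given STZ. The proximal tubule markers rose (17 of 19 members higher, median log2 difference 0.22, camera adjusted p = 0.0243). This set and the 4 others called had an adjusted p = 0.994 with an estimated correlation, and by either count, over all genes or over each list alone, 0 of their members passed. Slc5a2, the glucose transporter of the early proximal tubule, was at 239 ± 38.6 FPKM (n = 3) in STZ and 314 ± 29.7 after transfer (0.40 ± 0.12; adjusted p = 0.745). The thick ascending limb markers fell (8 of 9, -0.30, 0.0243), with Umod at 579.7 ± 63.9 and 396 ± 77.9. The adrenal cortex (8 of 8, -1.46, 0.0279), adipocyte (8 of 8, -0.44, 0.0378) and ribosomal protein sets (17 of 23, -0.10, 0.0378) fell. Cyp11b1 was at 0, 5.13 and 5.13 in STZ and 0, 0 and 0.030 after transfer. Among the clock genes, adjusted over the list alone, the activators Arntl (adjusted p = 0.0451) and Npas2 (0.0461) fell and Per2 (0.0451) and Hlf (0.0451) rose, against 0 over all genes. Arntl was at 6.02 ± 1.87 FPKM in STZ and 1.57 ± 0.225 after transfer.

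Limma called 14 genes lower and 0 higher, with 479 at an unadjusted p under 0.05. All 14 are among the 19 genes that were higher in each control and STZ library than in any other. Prm1 (adjusted p = 5.82e-06), Tnp2, Prm2, Tnp1, Oaz3, Ldhc, Gsg1 and Spata4 were listed at 0 in the 3 libraries after transfer. Fabp9, Meig1, Odf1, Crisp2, Tcp11 and the predicted gene Gm3448 make up the rest, the last 4 named after their values were seen. H2-Eb1 was at 16.6 ± 5.85 FPKM after transfer and 1.44 ± 0.179 in STZ, which passed adjusted over the list alone (adjusted p = 6.12e-04) but not over all genes (0.0575). Without STZ+AOS-FMT 1 there were 9 called genes and without STZ+AOS-FMT 3 there were 8, and in a fit of these 6 libraries alone 0. Ldhc, Gsg1 and Meig1 were among those that lost their call without 1 library (adjusted p up to 0.0672), and quantile normalization lost Gsg1 (0.0531) and Meig1 (0.0931). With control 3 and STZ 1 both left out Meig1 (0.0571) and the adipocyte set (0.129) were not called. Leaving out STZ+AOS-FMT 2 gave 0 called sets, leaving out STZ 3 gave 2, neither among the 5, and leaving out STZ 1 or STZ 2 gave 8, with 4 of the 5 among them. For adipocytes the call was lost without STZ 1, STZ 3 or STZ+AOS-FMT 2 (adjusted p up to 0.554) and for the adrenal cortex without STZ 2, STZ 3, STZ+AOS-FMT 1 or STZ+AOS-FMT 2 (adjusted p up to 0.0714). For the proximal tubule the call was lost without STZ 3 or STZ+AOS-FMT 2 (adjusted p up to 0.846, direction turned without STZ 3) and for the thick ascending limb without STZ 3 or STZ+AOS-FMT 2 (adjusted p up to 0.102). For ribosomal proteins the call was lost without STZ 3, STZ+AOS-FMT 2 or STZ+AOS-FMT 3 (adjusted p up to 0.643). Median-of-ratios rescaling lost the calls of the proximal tubule (0.0529), the adrenal cortex (0.0582) and adipocytes (0.0959), and quantile normalization those of the adrenal cortex (0.0623), adipocytes (0.0772) and ribosomal proteins (0.384).

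The comparison of STZ+control-FMT with STZ asks what a transfer from control donors did. The cell cycle genes rose (14 of 14 members higher, median log2 difference 0.30, camera adjusted p = 2.29e-05). With an estimated correlation this set and 3 of the others called had an adjusted p = 0.862 and the immediate early genes an adjusted p = 0.873, and 0 of the members of these 5 sets passed over all genes or adjusted over the list alone. Mki67, a marker of dividing cells, was at 0.533 ± 0.431 FPKM (n = 3) in STZ and 1.17 ± 0.114 after transfer (0.54 ± 0.18). The erythroid (7 of 7, 0.90, 0.00203) and the stromal and smooth muscle markers (8 of 10, 0.34, 0.00362) rose, with Col1a1, a chain of type I collagen, at 3.22 ± 0.326 and 6.97 ± 1.91. The immediate early genes rose (11 of 12, 0.46, 0.00971), Fos being at 3.65, 0.670 and 8.89 in STZ and 4.14, 47.3 and 4.08 after transfer, and the adrenal cortex markers fell (8 of 8, -1.55, 0.00362).

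H2-Eb1 was at 12.9 ± 8.80 FPKM (n = 3) after transfer and 1.44 ± 0.179 in STZ, which passed adjusted over the list alone (adjusted p = 0.00338) but not over all genes (0.265). Limma called 13 genes lower and 0 higher, with 281 at an unadjusted p under 0.05. All 13 are among the 19 genes that were higher in each control and STZ library than in any other. Prm1 (adjusted p = 5.82e-06), Tnp2, Prm2, Tnp1, Fabp9, Ldhc, Gsg1 and Spata4 were listed at 0 after transfer. Dbil5, a testis member of the acyl-CoA binding protein family, was at 2.98 ± 0.845 FPKM in STZ and 0.637 ± 0.0924 after transfer (-1.26 ± 0.21, adjusted p = 0.0275). It lost its call without any 1 of the transfer libraries, STZ 1 or STZ 3 (up to 0.221), and so did Ldhc and Gsg1 without 1 library or another (up to 0.0811). Quantile normalization lost Gsg1 (0.0509), and with control 3 and STZ 1 both left out Dbil5 (0.139) and the stromal set (0.276) were not called. The others were Oaz3, Odf1, Crisp2 and Gm3448, of which the last 3 were named after their values were seen. Without STZ+control-FMT 1, 2 and 3 there were 8, 7 and 7 called genes, and in a fit of these 6 libraries alone 0. The cell cycle and adrenal sets were called without each library in turn. For stroma and smooth muscle the call was lost without STZ 1, STZ+control-FMT 1 or STZ+control-FMT 3 (adjusted p up to 0.261) and for erythroid cells without STZ 2 or STZ+control-FMT 3 (adjusted p up to 0.165). For the immediate early genes the call was lost without STZ 2 or STZ+control-FMT 2 (adjusted p up to 0.808, direction turned without STZ+control-FMT 2). Leaving out STZ 1 gave 10 called sets, STZ 3 gave 9 and STZ+control-FMT 2 gave 8.

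The comparison of STZ+AOS-FMT with STZ+control-FMT asks whether the donor mattered once transfer was held equal. The adipocyte markers fell with AOS-labelled donors (8 of 8 members lower, median log2 difference -1.06, camera adjusted p = 2.83e-05). They are markers of fat cells, and whether the samples differed in how much fat tissue they held was not tested. With an estimated correlation the adjusted p was 0.730 for this set and 4 of the 10 others called, 0.130 for organic ion transport, 0.881 for the proximal tubule and 0.909 for the matrix, cell cycle, podocyte and thick ascending limb sets. Cidea (chromosome 18, 67343604 to 67367785), a lipid droplet protein of brown fat, was at 10.2 ± 5.52 FPKM (n = 3) with control donors and 0.817 ± 0.415 with AOS-labelled donors (-2.53 ± 0.65). Its adjusted p was 1 over all genes and 0.0119 adjusted over the list alone, where it was the 1 gene of this set to pass. The immediate early genes fell (11 of 12, -0.58, 1.55e-05), Egr1 being at 6.42, 96.9 and 9.06 with control donors and 2.55, 2.67 and 3.49 with AOS-labelled donors. Stromal and smooth muscle (10 of 10, -0.39, 4.05e-04), matrix (15 of 17, -0.26, 0.00165), erythroid (7 of 7, -0.85, 0.00284), B and plasma cell (4 of 4, -0.46, 0.0179), cell cycle (13 of 14, -0.16, 0.0179) and thick ascending limb sets (6 of 9, -0.18, 0.0311) fell as well. Organic ion transport (13 of 14, 0.18, 0.00183), proximal tubule (16 of 19, 0.13, 0.00183) and podocyte markers (9 of 10, 0.21, 0.0273) rose, Slc22a8 being at 88.9 ± 36.8 and 140.1 ± 24.8.

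Over all genes limma called 0 between the donors, 209 had an unadjusted p under 0.05, and the count was 0 under both other scalings. The groups did not overlap for 11.2% of genes, where chance gives 10%. The adipocyte and organic ion sets were called without each library in turn. Without STZ+control-FMT 1, 7 sets were called. For B and plasma cells the call was lost without STZ+AOS-FMT 1 or STZ+control-FMT 1 (adjusted p up to 0.540) and for the cell cycle without STZ+AOS-FMT 1, STZ+AOS-FMT 3, STZ+control-FMT 1 or STZ+control-FMT 2 (adjusted p up to 0.173). For the proximal tubule the call was lost without STZ+AOS-FMT 2 or STZ+control-FMT 3 (adjusted p up to 0.115) and for the thick ascending limb without STZ+AOS-FMT 2, STZ+AOS-FMT 3, STZ+control-FMT 2 or STZ+control-FMT 3 (adjusted p up to 0.269). For podocytes the call was lost without STZ+AOS-FMT 3, STZ+control-FMT 1 or STZ+control-FMT 2 (adjusted p up to 0.205) and for stroma and smooth muscle without STZ+control-FMT 1 (adjusted p = 0.0819). For matrix the call was lost without STZ+control-FMT 1 (adjusted p = 0.159) and for the immediate early genes without STZ+control-FMT 2 (adjusted p = 0.257). For erythroid cells the call was lost without STZ+control-FMT 3 (adjusted p = 0.244).

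The 3 treatments given to STZ mice share the STZ samples as their reference. Both transfers had 12 called lower genes in common, where independent lists would share 0.0144, and all 14 and 13 genes called lower after the transfers were also lower in STZ+AOS. Each belongs to the 19 genes that were higher in each control and STZ library than in any other. Being lower in the treated groups was part of that choice, so this overlap is partly built in. Part of the sharing between treatments may come from the shared reference. Over all genes, the differences of both transfers correlated at r = 0.626 across genes, which are not independent replicates, and 0.494 was obtained in data simulated without any effect but with the shared reference. The covariance was 0.0296, against a simulated 0.0291. For STZ+AOS with the transfers r was -0.0292 (AOS-labelled donors, simulated 0.476) and 0.143 (control donors, simulated 0.50). The simulated values come from a single draw with noise independent for each gene, whereas genes vary together in the real samples. They therefore do not settle how much of r or of the covariance the shared reference gives. A position of the treated samples between control and STZ, planned from pairs of held-out libraries, could not be formed. In genes chosen without them, held-out STZ samples lay below held-out controls, with a mean gap of -0.210 over 9 pairs (SD 0.328), and above them in 3 of 9 pairs. The pair of control 3 and STZ 1 gave -0.968, and the other 8 a mean of -0.116 (SD 0.176). In these 8 pairs 0 genes were called among the libraries kept in, so the genes were taken by rank. Over the 6 pairs that do not hold out control 3 the mean was -0.127.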

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

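The tests of explanations in this part were all chosen after the results were seen; the interaction test was planned. What raised the results below is a difference between groups: by the test of the interaction, 10 sets of genes passed for a difference in the effect of AOS with and without STZ. Chance is not excluded as their source, since 72 of 100 regroupings of the 12 libraries gave as many sets, with a highest other of 20. Relative to the other genes, the response to AOS was lower with STZ than without it for the proximal tubule markers (camera adjusted p = 1.31e-14), nuclear oxidative phosphorylation (5.64e-08), the androgen-responsive genes (6.17e-06), organic ion and xenobiotic transport (2.17e-05), heat shock (0.0307) and erythroid markers (0.0487). It was higher with STZ for adrenal cortex markers (0.00175), tubular injury (0.00350), matrix (0.00350) and stromal and smooth muscle markers (0.0295). The adrenal markers belong to another tissue, so their difference is not shown to be a response of the kidney to AOS. Whether the samples differed in how much adrenal tissue they held was not tested. With an estimated correlation only organic ion and xenobiotic transport passed (adjusted p = 0.0189). The rule for single samples far from the others was set for groups of at least 4 and was not applied to these groups of 3.

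Control 3 and STZ 1 each stood with the other group. A candidate explanation is an exchange of these 2 labels: on an axis formed without the control and STZ libraries, control 3 lay at 1.55 and STZ 1 at 0.00360, while the other 2 controls lay at 0.0670 and 0.0864 and the other 2 STZ libraries at 0.957 and 1.53. H2-Eb1 followed the labels instead, at 16.8, 13.5 and 13.0 FPKM in controls 1, 2 and 3 and 1.34, 1.34 and 1.65 in STZ 1, 2 and 3. Dilution of control 3 by adrenal tissue as the whole reason was argued against, since it would lower all kidney markers alike: its principal cell markers were a median 2.08 times the mean of controls 1 and 2 (9 of 9 above 1), while proximal tubule markers outside the androgen list, which went the way of dilution, were at 0.656 (5 of 18 above 1) and androgen-responsive genes at 0.205. A damaged control kidney together with an STZ sample without a response would give the same axis values, and this biological explanation was not tested.

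Spermatid transcripts were present in the control and STZ libraries and near 0 in the other 12. Testis RNA or reads in these 6 libraries may be the source but were not established: of 28 further spermatid and testis markers, 26 had a higher mean there and 7 were higher in each of the 6 than in each other library, and of the 18564 choices of 6 libraries 1349 gave as many with a higher mean (exact permutation p = 0.0727). A lowering by AOS does not account for the low values in the STZ+control-FMT libraries, whose label names no AOS. Prm1, Tnp2, Prm2, Tnp1, Fabp9, Ldhc and Spata4 were listed at 0 in them and Oaz3 was at 0.09 ± 0.09 FPKM. Whether AOS lowered these genes in the groups given it was not decided. In STZ+control-FMT they fell by 2.57 on the log2 scale against STZ (median of 8 genes). These genes were picked partly for being lower there, which fixed the sign in advance. Of the 9 genes called for AOS against control, a call made without that condition, 8 met it. Separate handling of the control and STZ libraries cannot be told apart from the treatments: 19 genes were higher in these 6 than in any other library, against at most 11 for the 14 other pairs of groups, and the labels give no batch.

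H2-Eb1 and its neighbour H2-Ea-ps were low in the 3 STZ libraries. Fewer antigen-presenting cells were argued against, since 9 further class II and antigen-presenting cell genes had a median log2 difference of 0.0465. A class II haplotype shared by these 3 samples may explain both genes, with H2-Ea-ps at a log2 difference of -2.61, but no genotype is given, so it cannot be told apart from an effect of STZ. The lowest of the 9 other libraries given STZ had 5.96 FPKM of H2-Eb1, above each STZ library, which leaves open that each added treatment restored the gene.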

How the results depend on the processing

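The tests over other splits, rescaling without Kap, Cyp11b1 as a covariate, the libraries left out for Cyp11b1, the pair left out together and the held-out gap were chosen after the data were seen; the other alternatives were planned. As reported, limma called 0 genes for STZ, 9 for AOS, 575 for STZ+AOS, 14 for STZ+AOS-FMT, 13 for STZ+control-FMT and 0 for the donors and the interaction, and camera 8, 9, 12, 5, 5, 11 and 10 sets in the same order. Of the results for named genes under an alternative, 1053 kept their direction and side of the threshold, 217 lost their call, 16 gained one and 0 turned; for called sets these were 866 kept, 334 lost and 23 turned. Of the counts, 191 stayed within 1.5 times and 98 moved further, as follows; the cause was not tested except where fewer genes or libraries were tested. With quantile normalization, 1 gene for STZ, 4 for AOS and 128 for STZ+AOS, and 17 sets for AOS, 3 for STZ+AOS-FMT and 17 for the interaction were called. With median-of-ratios rescaling, 14 sets for AOS, 3 for STZ+AOS-FMT and 16 for the interaction were called. Without a filter, 7 genes for STZ, 40 for AOS, 1126 for STZ+AOS, 179 for STZ+AOS-FMT, 163 for STZ+control-FMT and 3 for the interaction, and 4 sets for STZ, 5 for AOS and 1 for STZ+AOS-FMT were called. With a mean of at least 5 FPKM, 0 genes for AOS, 339 for STZ+AOS, 0 for STZ+AOS-FMT, 0 for STZ+control-FMT and 1 for the interaction, and 4 sets for STZ and 3 for STZ+control-FMT were called. With weights for each library, 984 genes for STZ, 22 for AOS, 1479 for STZ+AOS, 88 for STZ+AOS-FMT, 20 for STZ+control-FMT and 56 for the interaction were called. With a pseudocount of 0.1, 242 genes for STZ+AOS were called. With a pseudocount of 5, 1 gene for AOS and 952 for STZ+AOS, and 3 sets for STZ+AOS-FMT were called. In a fit of only the groups compared, 2 genes for STZ, 5 for AOS, 0 for STZ+AOS, 0 for STZ+AOS-FMT and 0 for STZ+control-FMT, and 8 sets for STZ+control-FMT were called.

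With an estimated correlation, 0 sets for STZ, 0 for AOS, 1 for STZ+AOS, 0 for STZ+AOS-FMT, 0 for STZ+control-FMT, 0 for the donors and 1 for the interaction were called. With fry, 0 sets for STZ, 0 for AOS, 2 for STZ+AOS, 0 for STZ+AOS-FMT, 0 for STZ+control-FMT, 0 for the donors and 0 for the interaction were called. With Cyp11b1 as a covariate, 7 genes for STZ+AOS, and 7 sets for STZ+AOS and 11 for STZ+control-FMT were called. With the libraries with Cyp11b1 above 100 FPKM left out, which are control 3 and STZ+AOS 1 and 3, 4 genes and 5 sets for AOS were called. The count of genes for STZ+AOS moved too, but it rested on STZ+AOS 2 alone and is not given. With control 3 and STZ 1 both left out, 1105 genes for STZ and 20 for STZ+AOS, and 5 sets for AOS, 8 for STZ+AOS-FMT and 11 for STZ+control-FMT were called. Limma without trend and robust and rescaling without Kap moved none of the counts past 1.5 times. The direction of a set turned with quantile normalization for the oxidative phosphorylation set for STZ (0.986), given as adjusted p. With Cyp11b1 as a covariate it turned for the androgen-responsive set for AOS (0.973), the adrenal set, of which Cyp11b1 is a member, for STZ+AOS (0.913), the erythroid set for STZ+AOS (0.402), the androgen-responsive set for STZ+AOS (0.153), the proximal tubule set for STZ+AOS-FMT (0.868), the adrenal set for the interaction (0.892), the erythroid set for the interaction (0.264), the androgen-responsive set for the interaction (0.264) and the heat shock set for the interaction (0.453). With the libraries above 100 FPKM left out it turned for the adipocyte set for STZ (0.646), the Y-linked set for AOS (0.745), the androgen-responsive set for AOS (0.822) and the erythroid set for the interaction (0.880), and with control 3 and STZ 1 both left out for the adipocyte set for STZ (0.733), the Y-linked set for AOS (0.605) and the androgen-responsive set for AOS (0.613). The cause was not tested.

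Leaving out 1 library at a time gave 0 to 0 for STZ, 4 to 7 for AOS, 11 to 3349 for STZ+AOS, 8 to 14 for STZ+AOS-FMT, 7 to 12 for STZ+control-FMT, 0 to 0 for the donors and 0 to 3044 for the interaction as the range of gene counts, and 6 to 13 for STZ, 5 to 17 for AOS, 9 to 15 for STZ+AOS, 0 to 8 for STZ+AOS-FMT, 5 to 10 for STZ+control-FMT, 7 to 11 for the donors and 8 to 14 for the interaction as that of sets. The direction turned for the endothelial set for STZ without control 1 (0.532), the adipocyte set for STZ without control 3 (0.625), the Y-linked set for AOS without control 3 (0.682), the androgen-responsive set for AOS without control 3 (0.807), the proximal tubule set for STZ+AOS-FMT without STZ 3 (0.846) and the immediate early set for STZ+control-FMT without STZ+control-FMT 2 (0.717). Over the libraries left out, adjusted p ranged from 9.10e-04 to 0.532 for the endothelial set, from 3.41e-05 to 0.625 for the adipocyte set, from 4.41e-04 to 0.682 for the Y-linked set, from 5.16e-06 to 0.807 for the androgen-responsive set, from 2.21e-07 to 0.846 for the proximal tubule set and from 4.17e-06 to 0.808 for the immediate early set. For STZ+AOS the count was 3349 without STZ 3 and 1392 without STZ+AOS 2, and 3044 and 793 for the interaction. The cause was not tested.

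The labels give no pairing. Over 45 pairs of libraries with the same replicate number, Pearson's r across genes of their deviations from the group mean was above 0.1 in 15 and ranged from -0.258 to 0.667, with a mean of 0.0414. The mean for different numbers was -0.0215. Deviations from a group mean add up to 0, which largely fixes this mean by the other, so it is no separate baseline. With a mean this low and no pairing in the labels, the numbers were not taken to pair the samples. Genes are not independent replicates in such an r. With the number as a block, the gene counts were 0 for STZ, 6 for AOS, 1116 for STZ+AOS, 13 for STZ+AOS-FMT, 13 for STZ+control-FMT, 0 for the donors and 0 for the interaction, and the counts of sets 7 for STZ, 10 for AOS, 12 for STZ+AOS, 6 for STZ+AOS-FMT, 5 for STZ+control-FMT, 12 for the donors and 9 for the interaction.

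The 6 libraries of a comparison split into groups of 3 in 10 ways, too few for a share under 0.05. The number of called genes in the real split and the highest in any other, with the number of splits that gave as many in parentheses, was 0 for STZ against at most 4642 (10), 9 for AOS against at most 0 (1), 575 for STZ+AOS against at most 1 (1), 14 for STZ+AOS-FMT against at most 1 (1), 13 for STZ+control-FMT against at most 0 (1) and 0 for the donors against at most 0 (10). For sets it was 8 for STZ against at most 18 (7), 9 for AOS against at most 19 (8), 12 for STZ+AOS against at most 16 (4), 5 for STZ+AOS-FMT against at most 12 (9), 5 for STZ+control-FMT against at most 11 (8) and 11 for the donors against at most 17 (2). The split of control 1, control 2 and STZ 1 from the others called 4642 genes, which points to a structure of the samples that the labels of control and STZ do not follow. Of 100 regroupings of the 12 libraries of the interaction, 72 gave as many sets as the real 10 (highest other 20), so chance is not excluded for the sets. A count of 0 genes is matched by any regrouping (100 of 100, and likewise for STZ and the donors above), so it decides nothing, while the highest other, 6438, again points to a structure of the samples.

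The position of the treated groups between control and STZ could not be formed, so it and its leave-one-out values were not run. The gap of the held-out STZ libraries over the held-out controls was -0.210 (SD 0.328 over 9 pairs), -0.186 with quantile normalization, -0.182 with median-of-ratios rescaling, -0.100 without a filter and -0.247 and -0.256 with 200 and 1000 genes, all within that SD of each other. Genes and sets under the stricter filter have no value there. The unknown depth leaves open how far values near 0, such as those of the spermatid genes, are set by single reads.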

Other observations

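Antioxidant genes split in STZ+AOS against STZ. Hmox1, the heme-degrading enzyme induced by oxidants, rose (log2 difference 1.28 ± 0.32; limma adjusted p = 0.0475), with 33.7, 53.6 and 76.4 FPKM in STZ and 140.4, 68.9 and 214 in STZ+AOS. Adjusted over the list alone, 3 genes of the NRF2 and antioxidant list rose, Hmox1, Srxn1 (limma adjusted p = 0.0304) and Txnrd1 (0.0439), and 4 fell, the peroxide-removing enzymes Gpx1, Cat and Prdx1 (0.0304 each) and the dismutase Sod1 (0.0439); over all genes only Hmox1 passed. The list as a whole was not called (camera adjusted p = 0.0673), with a median of 0.03 and a test direction of lower. Among the glucose handling genes, the gluconeogenic enzyme Fbp1 fell (adjusted p = 0.0478), and adjusted over the list alone the fructose pathway enzymes Sord (0.0423) and Khk (0.0285) fell too, while the glucose transporter Slc2a1 and the insulin signalling gene Irs2 rose (0.0423 each); the list missed the threshold at 0.0546, with a median of 0.08 and a test direction of lower. Pdk4, which holds back glucose oxidation, rose from 6.35 ± 3.83 to 21.2 ± 5.78 FPKM (n = 3; limma adjusted p = 0.0370). The calls over all genes are among the 575 of this comparison, a count that was 11 without STZ 1, 11 without STZ 2 and 15 without STZ+AOS 1. Hmox1, Fbp1 and Pdk4 did not pass without any 1 of these 3 libraries (limma adjusted p up to 0.220), nor Hmox1 and Pdk4 without STZ+AOS 3 (0.0748 and 0.0609). Hmox1 (0.0579) and Fbp1 (0.0794) did not pass after quantile normalization, nor Hmox1 after median-of-ratios rescaling (0.0553). Hmox1 was highest in STZ+AOS 1 and 3, as were the adrenal markers (Cyp11b1 at 316, 14.3 and 276 FPKM), and with Cyp11b1 as a covariate, chosen after the data were seen, Hmox1 (0.758), Fbp1 (0.533) and Pdk4 (0.703) did not pass. The log2 difference was then 0.68 in place of 1.28 for Hmox1 and 1.05 in place of 1.68 for Pdk4. For Fbp1 it was -0.84 in place of -0.65, so its call was lost without a smaller difference.

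Fga, which encodes a chain of fibrinogen, rose in STZ+AOS against STZ (limma adjusted p = 0.0486), at 4.06, 8.51 and 8.02 FPKM in STZ and 29.1, 8 and 49.0 in STZ+AOS. It lost its call without STZ 1, STZ 2, STZ+AOS 1 or STZ+AOS 3 (adjusted p up to 0.224), after quantile normalization (0.0891) and after median-of-ratios rescaling (0.0566). It was highest in STZ+AOS 1 and 3, as were the adrenal markers, and did not pass with Cyp11b1 as a covariate (0.805). For the interaction, the genes that passed adjusted over the list alone include Fga, Saa1 and C3 (limma adjusted p = 0.0257 each) with positive differences and Cfb (0.0478) with a negative one, against 0 over all genes. C3, the central complement protein, was at 29.1, 20.7 and 110.1 FPKM in the controls, 7.29, 8.98 and 17.5 in AOS, 10.8, 58.8 and 86.8 in STZ and 137, 81.6 and 64.9 in STZ+AOS. Cd14, the endotoxin co-receptor, passed among the macrophage and monocyte markers adjusted over the list alone (limma adjusted p = 0.0353), with 6.01, 12.5 and 20.2 FPKM in STZ and 158, 23.8 and 30.2 in STZ+AOS. Cyp1b1 (0.0125) and Ahr (0.0357) passed in the same way among the aryl hydrocarbon receptor genes.

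Of the 41 sets, 14 were called in no comparison. Their lowest camera adjusted p over the 7 comparisons was 0.0546 for glucose handling, 0.0673 for NRF2 and antioxidant, 0.107 for circadian clock, 0.113 for unfolded protein and integrated stress response, 0.128 for liver, pancreas and muscle markers, 0.139 for macrophage and monocyte markers, 0.141 for interferon response, 0.158 for principal cell markers, 0.186 for complement and acute phase, 0.286 for renin-angiotensin, 0.404 for female-biased kidney genes, 0.475 for hypoxia targets, 0.546 for antigen presentation and 0.637 for aryl hydrocarbon receptor targets.

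Dbp, a clock output gene, was at 114, 112 and 113 FPKM in STZ+AOS-FMT and 51.1, 78.2 and 57.0 in STZ+control-FMT, and in the other groups spread from 2.76 to 90.6; the times of collection are not given in the sources used here. Hbb-bs, a globin gene of red cells, ranged from 0 to 3258 FPKM over the 18 libraries, with 1.07, 1.21 and 2.60 in STZ+AOS. Cyp4a14, a fatty acid hydroxylase induced through PPAR alpha, was at 8.56, 2.42 and 227 FPKM in the controls and 1.26, 34.0 and 375 in STZ, and Prlr, which is higher in female mouse kidney, at 0.610, 0.630 and 9.08 and 0.740, 1.35 and 6.24. Ddx3y, a Y-linked gene, was between 7.32 and 15.4 FPKM in all 18 libraries. These genes were chosen after their values were seen.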
